A study of Mus musculus with 4 samples.

How the data were processed

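The data were 4 single-cell RNA libraries, 1 each for control IgG, anti-PD-1, anti-LIF and both antibodies (combo). Per the labels, female C57BL/6 mice of 6 to 7 weeks carried subcutaneous Pan02 tumours and were grouped at a tumour size of about 50 mm3. They received 200 µg anti-PD-1 per injection and 25 mg/kg IgG or anti-LIF, 3 times a week. Per the labels, 3 samples were combined for each library, and no animal can be told from another. Libraries were made with the SeekOne MM 3' kit and sequenced on 1 of a pair of instruments. The labels do not say which library went on which instrument. Removal of debris and dead cells and DNase treatment were optional per the labels, again without saying for which library.

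The deposited matrices hold counts: whole-number UMI counts per gene and cell barcode, with no normalization. The deposited barcode and feature lists hold other content, namely 1 barcode per cell and the Ensembl identifier and symbol of each of 32285 genes. The submitters' processing notes name the mm10 build and Seurat 4.0.3 without a role for it. The aligner, the counter and the rule for calling cells were not given in the sources used here. Of the 32285 identifiers, 32235 (99.8%) are in the GENCODE M21 annotation, which gave gene positions.

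Depth was 20393 barcodes and 111164731 UMIs in control, 15191 and 67503066 in anti-PD-1, 15046 and 57720774 in anti-LIF, and 17472 and 94984486 in combo. The lowest UMI count of a barcode was 623 in control and 500 in the other libraries. Barcodes with at least 200 genes and at most 20% mitochondrial UMIs were kept: 91.4% in control, 94.7% in anti-PD-1, 93.1% in anti-LIF and 93.8% in combo, 63439 cells in all. The median mitochondrial share of kept cells was 9.28%, 8.45%, 7.86% and 7.25% in that order. Scrublet, run per library in scanpy 1.11.5, called 0, 3, 1 and 0 doublets. This is under 0.5% of the cells, so the caller did not work here, and doublets remain in the data. Clusters with the leading genes of 2 classes were left unnamed.

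Counts were scaled to 10000 per cell and log-transformed. The 2000 most variable genes, 30 principal components, 15 neighbours and Leiden clustering at resolution 1 (leidenalg 0.10.2, igraph 0.11.9) gave 39 clusters over all libraries together. A cluster was named by the fixed marker list with the highest mean log2 CPM over the median of clusters, if that score was at least 0.8, at least 3 markers were detected, and no other class reached 0.7 of it. The score thresholds, the use of Xist and a list of host gland genes (Csn3, Wfdc18, Prlr, Ltf, Bpifa2, Smr3a, Amy1, Pip) were set after the data were seen. Under the Xist rule a cluster with Xist below 0.25 of the median over clusters was taken as grafted tumour. The naming rule had 2 versions, and the first was replaced after its cluster names were seen. The first used marker scores alone, with Xist only able to take the cancer cell name away. It called cluster 4 fibroblast (fibroblast score 1.19, cancer cell score 0.665) and left cluster 0 unnamed as mixed with fibroblast. It also named clusters 26 (T cell), 28 (macrophage), 35 (cancer cell) and 37 (neutrophil), which the rule used here leaves unnamed. Cluster 4 held 2854 control, 813 anti-PD-1, 119 anti-LIF and 178 combo cells. The 10 unnamed clusters held 5.68% of control, 4.87% of anti-PD-1, 3.85% of anti-LIF and 5.73% of combo cells. T and NK cells were clustered again with 1500 variable genes and named by fixed subset markers, with score and CPM thresholds set after the sub-clusters were seen. The subset rule also had 2 versions: the first left unnamed each sub-cluster with a marker of another class among its top 10 genes, and was replaced because it left many CD8 T cells unnamed. The rule used leaves out sub-clusters with Krt18, C1qc or Col3a1 RNA. Results under both first versions are given with the alternatives. The share of fibroblasts was not computed under them. Classes rebuilt in this way can differ from those of the study.

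Shares of cells carry exact Clopper-Pearson 95% intervals. Ratios of shares and of counts carry exact conditional intervals, and CPM values exact Poisson intervals (scipy 1.17.1, numpy 2.4.6, pandas 2.3.3, python 3.11.15). All of them cover counting error only, not the difference between animals. With 1 library per group no p-value, standard error or count of changed genes was computed. UMIs were summed per class and library and given as CPM of all UMIs of the class, with 0.5 counts added to each sum for log2 ratios. For a gene with 0 UMIs in control, the bound given as at least N-fold uses 3 counts in control. Each treated library was compared with control and the combo library also with each single antibody.

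Gene lists were fixed in advance: interferon gamma and MHC class I, type I interferon, MHC class II, STAT3 targets, LIF family, proliferation, hypoxia and glycolysis, apoptosis and p53, dissociation stress, haemoglobin, cytotoxic effectors, exhaustion, naive and memory T, inflammatory macrophage, alternative macrophage, complement and lipid macrophage, chemokines, suppressive neutrophil, contractile fibroblast, inflammatory fibroblast, collagen and matrix, epithelial, mesenchymal transition and endothelial activation. A list's value is the median log2 ratio of its members with at least 20 UMIs over both libraries, with an interval from 1000 Poisson redraws. Its rank among 10000 random lists matched on expression in 20 bins describes these libraries and is no test. The design, the lists, the markers and the rule for named genes were fixed before the data were examined.

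Named genes were chosen by that rule for the 3 largest named classes, which were cancer cells, macrophages with monocytes, and T cells. Per class and treatment these are the 4 genes with the highest and the 4 with the lowest log2 ratio whose interval excludes 0. They needed at least 50 UMIs over both libraries, at least 50 CPM in the higher library, and at least 1 part in 4 of the gene's highest CPM in any named class. Mitochondrial, ribosomal protein, haemoglobin, immunoglobulin and T cell receptor segment, Gm-numbered and Rik genes were left out. Lif, Lifr, Il6st, Socs3, Pdcd1, Cd274, Cxcl9, Cxcl10, Ccl2, Arg1, Mrc1, Gzmb, Ifng, Foxp3, Cd8a and the leading members of lists were reported whatever their value.

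The intervals were tested on simulated data for anti-LIF against control in macrophages, over 9859 genes. The counts were independent Poisson draws around the library sums, the model that the intervals assume, so this checks the computation alone. UMIs that lie together in few cells were not simulated. For such genes the intervals are too narrow: 10 anti-LIF T cells held 86.1% of the Ccl1 UMIs. For 9659 unchanged genes 96.1% of the intervals covered the true ratio. Intervals excluded 0 on the right side for 61.2% of 67 genes changed 1.5-fold, 83.6% of 67 genes changed 2-fold and 100% of 66 genes changed 4-fold. A list of 20 genes raised 2-fold had a median log2 ratio of 0.96. Of unchanged lists, 3% fell outside percentiles 2.5 to 97.5. Clopper-Pearson intervals covered the true share in 94.9% of draws.

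Alternatives for shares were a mitochondrial limit of 10%, at least 500 genes, doublets kept, resolutions 0.5 and 2, a class given to each cell, immune cells as the whole, and only cells with at least 1000 UMIs. The last left out 3467 control, 4500 anti-PD-1, 4482 anti-LIF and 4297 combo cells with fewer UMIs. The counts of the cells left were not thinned. Alternatives for expression were TMM scaling (edgeR 4.0.16), median-of-ratios scaling (DESeq2 1.42.0, R 4.3.3), CPM without mitochondrial, ribosomal protein and haemoglobin genes, no minimum of UMIs, 5 counts added, and the mean over cells of each cell's CPM. Added after the data were seen were a common UMI minimum, removal of the 6% of cells with the highest doublet scores, cancer and immune classes as the whole, the naming rules written first, and lists within single fibroblast clusters and CD8 T and NK sub-clusters with at least 20 cells in both libraries. So were lists within cancer cell, endothelial, neutrophil, dendritic and T cell clusters, single genes within macrophage, T cell, dendritic cell, CD8 T and Treg clusters, the subtraction of T cell and macrophage RNA from dendritic cells, and share ratios of combo against each single-antibody library under the alternatives for shares. Figures were drawn with matplotlib 3.10.9, and scikit-learn 1.9.0 was used for nearest neighbours. No paired comparison was made.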

Results

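Single cells from subcutaneous Pan02 tumours, a mouse pancreatic cancer line grown in female C57BL/6 mice, were profiled in 4 libraries. The mice received control IgG, an antibody against the checkpoint receptor PD-1, an antibody against the cytokine LIF, or both antibodies (combo). Cells of 3 tumours were combined into each library, so each group was 1 library and no difference between groups was tested. Intervals in brackets are 95% intervals for counting error only. After filtering, 18640 control, 14389 anti-PD-1, 14013 anti-LIF and 16397 combo cells remained. Their median UMI counts were 2171 in control, 1731 in anti-PD-1, 1675 in anti-LIF and 2288 in combo, and the barcodes with the fewest UMIs had more in control than elsewhere.

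Of the 39 cell clusters, 29 were placed in 12 classes by marker genes, and a class name means cells like that type. Cancer cells (16829), macrophages with monocytes (14133), T cells (11275) and fibroblasts (9162) were the most frequent classes. Xist, the transcript that silences 1 X chromosome in female cells, was at 2.13 CPM (counts scaled to a common total of UMIs) in the cancer cell class. It was between 70.5 and 235 CPM in 9 host classes and at 41.8 CPM in skeletal muscle cells. Among the cancer cell clusters it was at 14.1 CPM in cluster 0 and between 1.43 and 1.65 CPM in clusters 2, 4 and 8. Cluster 0 held 18.0% of cancer cells in control and 39.0%, 45.2% and 46.9% in anti-PD-1, anti-LIF and combo. Its cells were shallow, with a median of 875 UMIs against 8401, 9386.5 and 13295 in clusters 2, 4 and 8. The median per cancer cell was 7859.5 UMIs in control and 2852, 2178.5 and 2825 in anti-PD-1, anti-LIF and combo. A larger cluster 0 thus cannot be told apart from more shallow barcodes. Xist was at 11.6 CPM in the unnamed cluster 35, led by salivary gland genes, so low Xist alone did not single out grafted cells. The Y-linked genes Ddx3y, Eif2s3y, Uty and Kdm5d, also planned for this check, had 3 UMIs in all cells. They thus gave no positive marker of grafted cells. The low Xist level gave cluster 4, whose fibroblast markers outscored its cancer cell markers, its cancer cell name, by a rule set after the clusters were seen. With the rule written first, the cancer cell share was at 15.3% in control, 12.6% in anti-PD-1, 9.24% in anti-LIF and 9.53% in combo. Gene levels are CPM of the UMIs summed over the cells of a class in a library. All 3 ratios against control share the same control library. The median log2 ratio of all genes measured was not 0: against control it was 0.19 for anti-PD-1, 0.22 for anti-LIF and 0.20 for combo in cancer cells. It was 0.11 for each treatment in macrophages, and 0.11, 0.07 and 0.11 in T cells. A gene list near these values moved no more than genes at large.

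The comparison of anti-PD-1 with control asks what blocking the checkpoint alone went along with. The anti-PD-1 library held many more macrophages and fewer T cells than control. Macrophages and monocytes made up 30.8% of its cells against 2.88% in control (log2 ratio 3.42 [3.29, 3.55]). T cells made up 12.3% against 35.8% (log2 ratio -1.54 [-1.62, -1.47]). Neutrophils were at 4.93% against 2.74%, with a log2 ratio of 0.85 [0.69, 1.02] that ranged from 0.64 to 1.82 over the alternatives tried. NK cells were lower, at 0.827% against 3.03%, and antibody-secreting plasma cells were at 0.111% against 1.23%. Cancer cells were at 29.8% against 37.3%, with a log2 ratio of -0.32 [-0.38, -0.27] that ranged from -0.71 to -0.26. Shares within 1 library sum to 100, so a higher share of 1 class lowers the others.

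**Figure D1:**
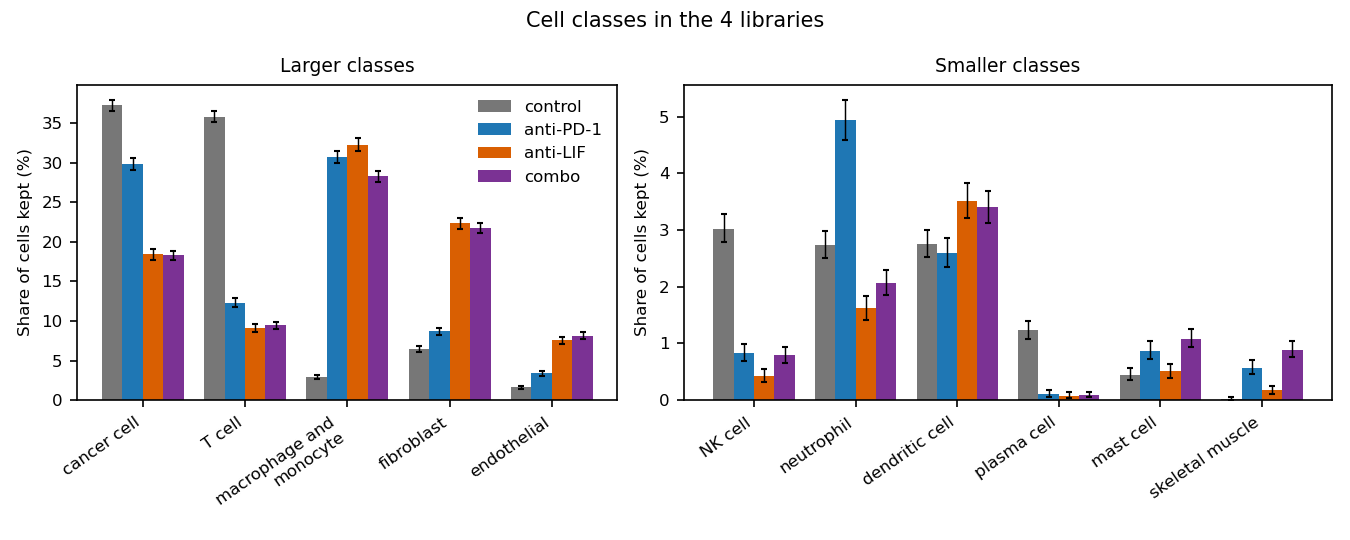
Share of all cells kept (percent, vertical axis) for each cell class in the control, anti-PD-1, anti-LIF and combo libraries; bars are 1 library each and error bars are exact 95% binomial intervals for counting error. Macrophages and monocytes were at 2.88% in control and between 28.3% and 32.3% in the treated libraries, while T cells were at 35.8% in control and between 9.13% and 12.3% in the treated ones.

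Within the T and NK cells, CD8 T cells kept their share under anti-PD-1, at 60.8% against 63.2% in control (log2 ratio -0.05 [-0.15, 0.04]). With the subset rule written first, which left more sub-clusters unnamed, that ratio was 0.39. Regulatory T cells (Treg), which restrain other T cells, were at 12.8% against 7.72% (log2 ratio 0.73 [0.51, 0.95]), but of all cells kept they were at 1.68% against 3.00%. In CD8 T cells the cytotoxic effector list had a median log2 ratio of 0.52 [0.50, 0.65]. The CD8 T cells of both libraries lay in different sub-clusters: sub-cluster 5 held 1.38% in control and 35.8% in anti-PD-1, and sub-cluster 1 held 31.6% and 7.14%. Within the 7 CD8 sub-clusters with enough cells the list was between 0.18 and 0.79. Its top members were Gzmc, a granzyme of killer cells (2.10), and the chemokine gene Ccl4 (1.28). Pdcd1, which encodes PD-1 itself, was at 458 CPM in CD8 T cells of the anti-PD-1 library and at 192 CPM in control. Gzmb, a granzyme that kills target cells, was at 866 against 716 CPM. Ifng, the gene for interferon gamma, was at 294 against 239 CPM. In the T cell class as a whole the exhaustion list was at 0.28 [0.19, 0.52], with Lag3 (1.58), the inhibitory receptor gene Tigit (1.36) and Pdcd1 (1.20) the farthest from 0.

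Cancer cells of the anti-PD-1 library carried less RNA of interferon gamma target genes and MHC class I genes, which present antigen to CD8 T cells. The list's median log2 ratio was -0.68 [-0.70, -0.66], and 21 of its 22 members were lower. Cd274, which encodes the PD-1 ligand PD-L1, was at 40.2 CPM against 91.9 CPM in control. The T cell attracting chemokine genes Cxcl9 (107 against 229 CPM) and Cxcl10 (234 against 569 CPM) were lower too. Within each of the 4 cancer cell clusters the list's median was between -0.84 and -0.55. The growth factor gene Ereg (-1.95 [-2.01, -1.89]) and the stem cell antigen gene Ly6a (-1.84 [-1.86, -1.82]) were among the genes with the lowest ratios. So were the haem-degrading enzyme gene Hmox1 (-1.84) and the LIF relative Il11 (42.3 against 152 CPM). Cancer cell cluster 4 was marked by Enpp2, Ptn, Ereg, Lif and Il11 and held 41.0% of cancer cells in control but 18.9% in anti-PD-1. Fewer cells of that cluster can carry only part of the lower Ereg (3.87-fold) and Il11 (3.59-fold). Levels of these genes within the cluster are not given here. The highest ratios were those of the chaperonin gene Cct7 (1.99), the phosphatase gene Ppp1ca (1.90), the p53-induced gene Trp53i11 (1.70) and the splicing factor gene Prpf19 (1.53).

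Macrophages of the anti-PD-1 library were more of the alternative kind, which goes with tissue repair. The alternative macrophage list was at 1.33 and the interferon gamma list at -0.61 [-0.69, -0.51]. Mrc1, a scavenging mannose receptor gene, was at 891 CPM against 281 in control. Arg1, whose product uses up arginine, was at 1038 against 373 CPM. Lyve1, a hyaluronan receptor gene of resident macrophages, had 0 UMIs in control macrophages and was at least 29.9-fold higher at 55.9 CPM. Cbr2 (2.71), an enzyme gene of resident macrophages, and the matrix gene Vcan (2.52) also had high ratios. Ccl24, a chemokine gene for eosinophils, was at 2.66, but 10 of 4430 cells held 62.0% of its UMIs, and the ratio was 1.16 with the mean over cells. The chemokine gene Ccl4 (-2.08), the antiviral gene Oasl1 (-1.96), Cd274 (-1.46) and the inflammatory cytokine gene Tnf (-1.44) had the lowest. The 536 control macrophages limit these ratios. Of them, 47.0% lay in cluster 3, 25.2% in cluster 6 and 21.6% in the monocyte cluster 10. In the anti-PD-1 library these clusters held 36.9%, 34.6% and 20.1%. Within these 3 clusters the alternative list stayed between 1.14 and 1.35.

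T cells of the anti-PD-1 library had higher RNA of the protease gene Ctsd (2.13), the calcium pump gene Atp2a3 (2.08), the peptidoglycan-degrading enzyme gene Pglyrp2 (2.03) and Ppp1ca (1.89). The membrane protease gene Tmprss6 (-1.70), the small GTPase gene Rasd2 (-1.68), the snoRNA host gene Snhg12 (-1.61) and the Golgi transport gene Bet1l (-1.27) were lower. Tmprss6 and Rasd2 marked CD8 T cell sub-cluster 0, which held 32.1% of CD8 T cells in control (1470 cells) and 13.8% in anti-PD-1 (159 cells). Type I interferon genes were higher in T cells, with a median of 0.81 [0.34, 1.02] and Oas1a (1.72) and Rsad2 (1.41), both antiviral, the farthest above 0. Within the T cell clusters 1, 7 and 11 it was at 0.57, 0.37 and 0.17, and cluster 11 held 13.7% of T cells against 28.8% in control, so part of the class value goes with the mix. Oasl1 was the exception at -1.90.

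The comparison of anti-LIF with control asks what neutralising LIF alone went along with. Macrophages were frequent and T cells rare here as well, and fibroblasts and endothelial cells were a larger part of the library. Macrophages and monocytes were at 32.3% against 2.88% (log2 ratio 3.49 [3.36, 3.62]). T cells were at 9.13% against 35.8% (log2 ratio -1.97 [-2.06, -1.88]). Fibroblasts were at 22.4% against 6.48% (log2 ratio 1.79 [1.69, 1.89]) and endothelial cells at 7.56% against 1.63% (log2 ratio 2.21 [2.03, 2.40]). The fibroblast difference depended on naming. Cluster 4, called fibroblast by the rule written first, was 15.3% of control and 0.849% of anti-LIF cells. The fibroblast ratio under that rule was not computed. Skeletal muscle cells, which lie around a subcutaneous tumour, were at 0.0268% of control, 0.570% of anti-PD-1, 0.171% of anti-LIF and 0.890% of combo cells, so part of the stroma need not be of the tumour. Cancer cells were at 18.4% against 37.3%, with a log2 ratio of -1.02 [-1.08, -0.95] that ranged from -1.17 to -0.63. Neutrophils were lower, at 1.62% against 2.74% (log2 ratio -0.75 [-0.99, -0.53]), a ratio that ranged from -1.10 to -0.17 over the alternatives tried. NK cells were at 0.428% against 3.03%.

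The T cells left in the anti-LIF library were of another mix. CD8 T cells made up 35.5% of T and NK cells against 63.2% in control (log2 ratio -0.83 [-0.97, -0.69]). Treg cells made up 19.7% against 7.72% (log2 ratio 1.35 [1.13, 1.57]). Naive T cells were at 20.4% against 8.80% and gamma delta T cells, an innate-like kind, at 10.2% against 2.72%. There were 1.80 CD8 T cells per Treg cell against 8.18 in control. Of all cells kept, Treg cells were not more frequent, at 1.88% against 3.00%.

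**Figure D2:**
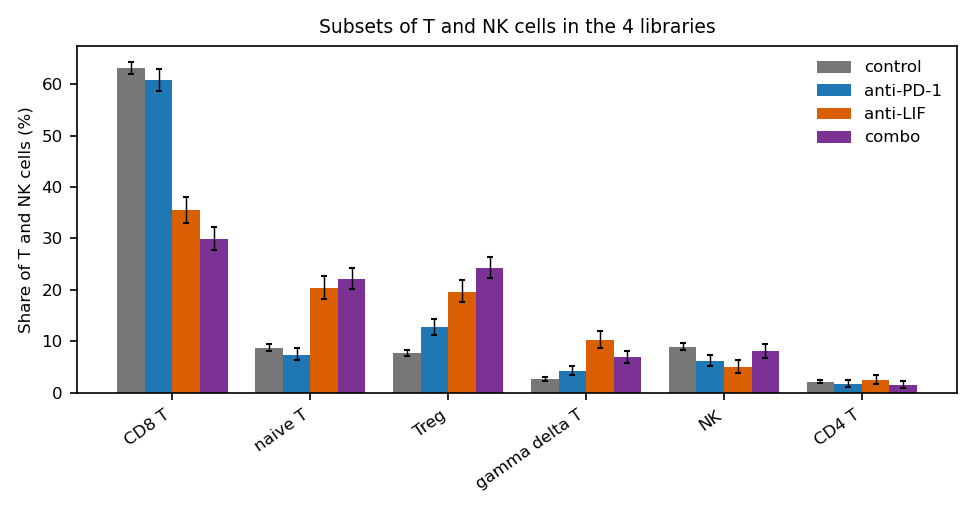
Share of T and NK cells (percent, vertical axis) for each lymphocyte subset in the control, anti-PD-1, anti-LIF and combo libraries; bars are 1 library each and error bars are exact 95% binomial intervals for counting error. CD8 T cells were at 63.2% and 60.8% in control and anti-PD-1 but at 35.5% in anti-LIF and lower still in combo, where Treg cells reached 19.7% and 24.3%.

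In the T cell class of the anti-LIF library the cytotoxic effector list was at -0.45 [-0.54, -0.24], with the pore-forming Prf1 (-1.77) and the granzyme genes Gzma (-1.55) and Gzmb (-1.24) the lowest. In CD8 T cells alone the list was at 0.14 [0.09, 0.26], so the class value goes largely with fewer CD8 T cells. The class value also depended on naming: it was -0.15 for the cytotoxic effectors list in the T cell class when cluster 26, which carries cancer cell and T cell genes, was counted as T cells. Gzmb was nevertheless lower in CD8 T cells, at 293 against 716 CPM. These cells lay in other sub-clusters, with 31.3% against 1.38% in sub-cluster 5, but Gzmb was lower there too (201 against 386 CPM) and in sub-cluster 2 (389 against 687 CPM), though not in sub-cluster 0 (770 against 707 CPM). In CD8 T cells as a whole Ifng was at 347 against 239 CPM and Pdcd1 at 289 against 192 CPM. Naive and memory genes were at 0.94 [0.88, 1.10] in the class, led by the interleukin 7 receptor gene Il7r (1.87), and at 0.49 and 0.72 within clusters 1 and 7. Cluster 1 held 36.3% of T cells here and 48.5% in control. The Treg-rich cluster 7 held 47.0% against 19.8%, the gamma delta cluster 23 10.7% against 2.86%, and the killer cell cluster 11 6.02% against 28.8%. The chemokine gene Ccl1 had the highest ratio (3.41 [3.17, 3.65]), from 34 of 1280 cells, and 10 of them held 86.1% of its UMIs. Lrrc32 (3.27), which holds latent TGF-beta on Treg cells, was at 215 against 44.8 CPM within Treg cells, so the larger Treg part is not all of it. The cytokine gene Il17a (2.43) was at 781 against 583 CPM within the gamma delta cluster 23, so most of its class value goes with that cluster's larger part. Dgat2, a fat-storing enzyme gene, was at 2.57. Gzmf, a granzyme gene, had 1 UMI in the anti-LIF library and a ratio of -7.29 [-13.18, -5.40]. Its 1623 control UMIs came from 160 of 6677 T cells, and 10 of them held 65.6%. Gzmf led CD8 sub-cluster 16, with 96 control cells and 1 anti-LIF cell. Tmprss6 also had 1 UMI (-5.99 [-11.88, -4.09]). Rasd2 (-3.01) and the interferon response gene Irf8 (-2.60) were lower too.

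Cancer cells of the anti-LIF library had much lower interferon gamma and MHC class I RNA than control. The list's median log2 ratio was -1.93 [-1.96, -1.77] and all 22 members were lower. Cd274 was at 11.1 against 91.9 CPM (-3.05 [-3.27, -2.84]), the chemokine gene Cxcl10 was at -2.82, and the interferon-induced GTPase genes Igtp (-2.78) and Gbp2 (-2.76) followed. Cxcl9 was at 44.2 against 229 CPM. The list was between -2.52 and -1.59 within clusters 0, 2 and 8, and at -0.43 in cluster 4, where the anti-LIF library had 119 cells. Type I interferon genes were at -1.25 [-1.33, -1.17], with Ifit3 (-2.61) and Rsad2 (-2.23) lowest. The genes with the lowest ratios were the membrane protein gene Ms4a4d (-4.21), the calcification inhibitor Mgp (-3.69 [-3.75, -3.62]), the metalloprotease gene Mmp19 (-3.60) and the cortisone-activating enzyme gene Hsd11b1 (-3.22). With a class given to each cell, Mmp19 was at -1.91 and Hsd11b1 at -2.22, and with the mean over cells Mgp was at -2.94.

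The placental prolactin relatives Prl2c3 (381 against 9.65 CPM; 5.30 [5.18, 5.42]) and Prl2c2 (509 against 16.6 CPM; 4.93 [4.84, 5.03]) had the highest ratios in cancer cells of the anti-LIF library. These genes are close paralogs, and reads can be shared among them. For Prl2c3, 10 of 2580 anti-LIF cancer cells held 32.2% of the UMIs, so its interval is too narrow. In macrophages of the same libraries Prl2c2 was at 6.28 against 1.87 CPM, far below the cancer cells. Prl2c2 marked cancer cell cluster 8, which held 28.3% of cancer cells against 14.6% in control. It was also higher outside that cluster, at 281 against 18.3 CPM in cluster 0. Cct7 (2.66) and Ppp1ca (2.60) came next.

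Proliferation genes were higher in the cancer cell class of the anti-LIF library, with a median of 1.18 [1.13, 1.22] and all 18 members higher. The nucleotide-making Rrm2 (1.69) and the cyclin gene Ccna2 (1.51) led. Within clusters the median was 0.59 in cluster 0, 0.07 in cluster 2, -0.14 in cluster 4 and 0.15 in cluster 8, so most of the class value goes with the mix of clusters. Cluster 8, whose leading genes include the list members Top2a, Rrm2 and Cdk1, held 28.3% of cancer cells against 14.6% in control. The low medians within clusters thus do not argue against more dividing cells. STAT3 target genes, through which LIF signals, were at -0.71 [-0.77, -0.66] in the class. Within clusters 0, 2, 4 and 8 they were at -0.16, -0.19, 0.08 and -0.42, so part of the class value goes with the mix and part remains, most in cluster 8. Pim1, a kinase gene in this list, was at -2.07. Cluster 4 held 4.61% of cancer cells against 41.0% in control.

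Macrophages of the anti-LIF library were strongly of the alternative kind. That list was at 2.03 [1.98, 2.25] and the interferon gamma list at -0.91 [-1.09, -0.77]. The haemoglobin scavenger receptor gene Cd163 (5.21 [3.68, 8.58], 2 UMIs in control), Ccl24 (3.27), the lectin gene Mgl2 (3.10) and the chitinase-like Chil3 (2.98) led the alternative list. Arg1 was at 1520 against 373 CPM and Mrc1 at 1156 against 281 CPM. Lyve1 was at least 89.0-fold higher at 167 CPM, the lectin gene Cd209f was at 6.47 [4.57, 12.36] with 1 UMI in control, and the endothelin receptor gene Ednrb was at 4.23. Cadm1, an adhesion gene (-3.54), the B cell survival factor Tnfsf13b (-3.28), the receptor gene Lilra5 (-3.10) and the DNA-degrading Dnase1l3 (-2.84) were lowest. Cxcl9 was at 277 against 1315 CPM. Clusters 3, 6 and 10 held 24.4%, 23.8% and 19.2% of these macrophages, and cluster 16, marked by Ccl8, Lyve1, Cd209f and Cd163, held 10.8% against 2.80% in control, and outside clusters 16 and 17 lay only 7.68% of the Lyve1, 2.77% of the Cd209f and 13.2% of the Cd163 UMIs. These genes thus lie mostly in a cluster that was larger in this library. Within it Lyve1 had no UMI in the 15 control cells and was at 1191 CPM in anti-LIF, Cd209f was at 625 against 19.9 CPM and Cd163 at 376 against 19.9 CPM, each from 1 control UMI, and these control cells are too few to part the larger cluster from a higher level within it. Within clusters 3, 6 and 10 the alternative list was still between 1.32 and 2.36.

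The comparison of combo with control asks what both antibodies together went along with. The combo library resembled anti-LIF alone in its cell classes. Macrophages and monocytes were at 28.3% against 2.88% (log2 ratio 3.30 [3.17, 3.43]), T cells at 9.43% against 35.8% (-1.92 [-2.01, -1.84]) and cancer cells at 18.3% against 37.3% (-1.03 [-1.09, -0.96]). The last ratio ranged from -1.21 to -0.47, and with a class given to each cell the cancer cell ratios of anti-PD-1, anti-LIF and combo were -0.71, -0.70 and -0.47. Fibroblasts were at 21.8% against 6.48% and endothelial cells at 8.12% against 1.63% (2.31). The fibroblast difference again depended on naming, since cluster 4 was 1.09% of combo and 15.3% of control cells. Neutrophils were at 2.07% against 2.74% (-0.40 [-0.61, -0.20]), a direction that reversed to 0.14 with only cells of at least 1000 UMIs and to 0.04 with cancer and immune cells as the whole. CD8 T cells were a smaller part of T and NK cells (log2 ratio -1.07 [-1.21, -0.94]) and Treg cells were at 24.3% (1.66 [1.47, 1.84]), which left 1.23 CD8 T cells per Treg cell. Of all cells kept, Treg cells were at 2.49% against 3.00%.

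**Figure D3:**
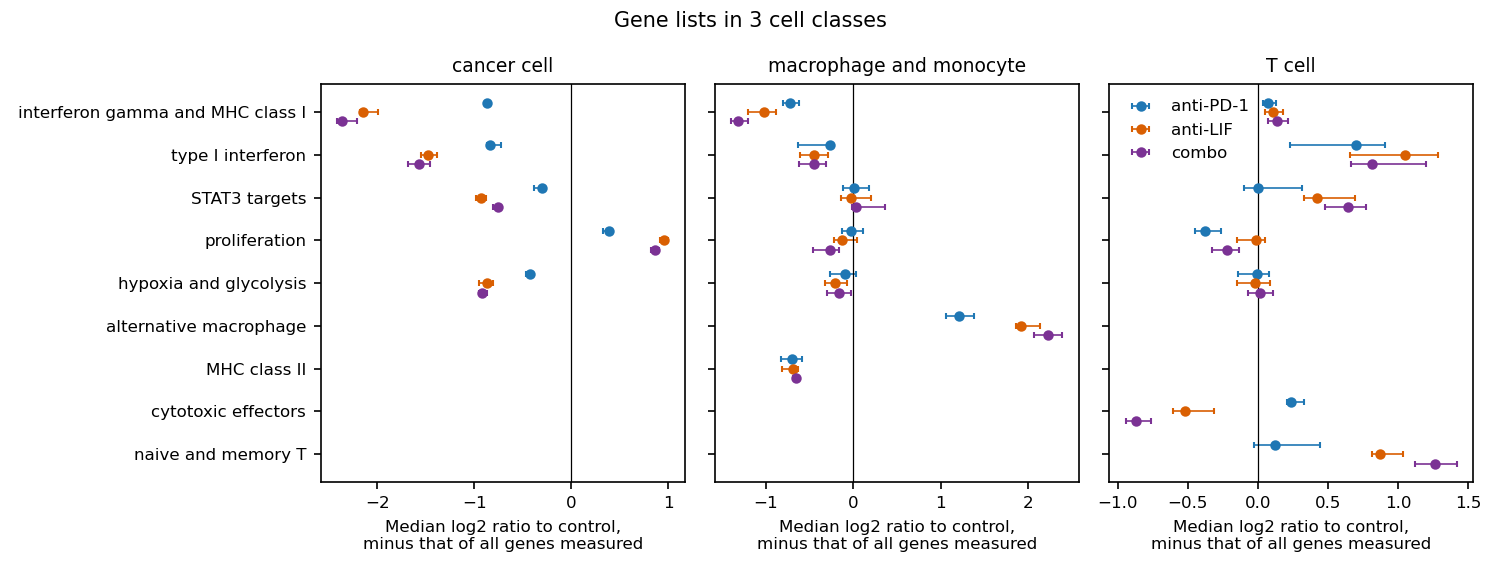
Median log2 ratio of CPM against control, minus that of all genes measured (horizontal axis), of fixed gene lists in cancer cells, macrophages and T cells. Points are list medians for the anti-PD-1, anti-LIF and combo libraries, and error bars are 95% intervals from Poisson redraws of the counts. Before that subtraction the interferon gamma and MHC class I list was at -0.68, -1.93 and -2.16 in cancer cells. The alternative macrophage list was at 1.33, 2.03 and 2.34 in macrophages before it.

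Cancer cells of the combo library had the lowest interferon gamma and MHC class I RNA of the 4 libraries, with a median of -2.16 [-2.21, -2.01] and all 22 members lower. Cd274 was at 10.2 against 91.9 CPM, Gbp2 at -2.96 and Igtp at -2.91. Cxcl9 was at 39.2 against 229 CPM and Cxcl10 at 82.8 against 569 CPM. The list was between -3.00 and -1.30 within the 4 clusters. Ms4a4d (-4.52), Hsd11b1 (-4.43), Mmp19 (-3.66) and Mgp (-3.56) again had the lowest ratios. With a class given to each cell, Hsd11b1 was at -2.86, Mmp19 at -2.05 and Mgp at -2.73. Apart from Dcpp1, Prl2c2 (4.15 [4.06, 4.24]) and Prl2c3 (3.20) had the highest, with the transmembrane protein gene Dynap at 1.98. Of the Prl2c3 UMIs in combo cancer cells, 36.5% lay in 10 of 3002 cells. Proliferation genes were at 1.06 [1.02, 1.11] in the class and between -0.83 and 0.35 within clusters. Cluster 0 held 46.9%, cluster 8, which such genes mark, 23.8%, cluster 2 23.4% and cluster 4 5.93% of the cells. Dcpp1, a salivary gland gene, had 0 UMIs in control cancer cells and was at least 1991-fold higher at 92.1 CPM, but its 2670 UMIs came from 9 of 3002 cells (0.300% [0.137, 0.568]). Combo macrophages had only 13 Dcpp1 UMIs, in 13 of 4641 cells (0.280%). The cancer cell value thus rests on 9 cells with many UMIs each, which do not describe the class. Whether these are gland cells placed in the class was not tested.

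Macrophages of the combo library had the highest alternative list, at 2.34, and the lowest interferon gamma list, at -1.21 [-1.29, -1.09]. Lyve1 was at least 154-fold higher at 288 CPM. The small secreted protein gene Mucl1, seen in 78 of 4641 cells, was at least 43.5-fold higher and the lectin gene Cd209g at least 34.0-fold higher. Neither had a UMI in control macrophages, and 10 combo cells held 69.8% of the Mucl1 UMIs. Cd209f was at 7.48 [5.59, 13.37], with 1 UMI in control. Cluster 16 held 15.4% of these macrophages and cluster 17, marked by Retnla and Mucl1, 14.0% against 2.05% in control. Within cluster 16 Lyve1 was at 1395 CPM and Cd209g at 343 CPM, and within cluster 17 Mucl1 was at 275 CPM, with no UMI of them in the 15 and 11 control cells there. Of the Cd209g UMIs, 0.634% lay outside these clusters. The control cells are too few to part a larger cluster from a higher level within it. Arg1 was at 1544 CPM and Mrc1 at 1299 CPM. Tnfsf13b (-3.47), Lilra5 (-2.79), Cadm1 (-2.70) and the testis-linked gene Zmynd15 (-2.52) were lowest.

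T cells of the combo library had the lowest cytotoxic effector list, at -0.76 [-0.84, -0.65], and the highest naive and memory list, at 1.37 [1.23, 1.52]. Gzmc (-2.61), the chemokine gene Ccl3 (-2.02) and Prf1 (-1.16) led the first, and the interleukin 7 receptor gene Il7r (2.24) the second. Within T cell clusters 1 and 7 the naive and memory list was at 0.65 and 0.91. Naive T cells made up 22.1% of T and NK cells against 8.80% in control, so part of the class value goes with the mix. In CD8 T cells alone the cytotoxic list was at 0.25 [0.12, 0.34]. Type I interferon genes in CD8 T cells were at 2.08 [1.49, 2.33], with Rsad2 (3.36) and Ifit1 (2.99) the highest. Within the 4 CD8 sub-clusters with enough cells and members it was between -0.10 and 0.80. Sub-cluster 12, which these genes mark, held 9.54% of CD8 T cells against 1.95% in control. Splitting cells by these genes lowers the values within sub-clusters, so those values do not argue against a higher level. Sub-cluster 5, with 38.2% of combo CD8 T cells, had no value. In T cell cluster 1, led by Cd8b1 and Cd8a among others, the list was at 1.25. Foxp3, the Treg master gene, was at 331 against 63.2 CPM in the T cell class, where the Treg-rich cluster 7 held 52.6% of cells, cluster 1 36.4%, cluster 23 7.18% and cluster 11 3.88%. The cytokine subunit gene Ebi3 (2.43), Dgat2 (2.88) and Foxp3 (2.39) had high ratios. BC037156 had 0 UMIs in control T cells and was at least 210-fold higher at 51.3 CPM, but it also reached 19.9 CPM over the combo cells outside the cluster led by the salivary gland genes Bpifa2 and Smr3a. BC037156 is itself among the leading genes of that cluster, and 10 of 1547 combo T cells held 64.5% of its T cell UMIs. Tmprss6 (-4.48), Gzmf (-4.12), Rasd2 (-3.61) and Snhg12 (-2.07) were lowest. Of the Gzmf UMIs in control, 65.6% lay in 10 of 6677 T cells. Ifng was at 107 against 206 CPM in the T cell class and at 236 against 239 CPM in CD8 T cells.

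The comparison of combo with anti-PD-1 asks what adding anti-LIF to the checkpoint antibody went along with. The combo library had more fibroblasts and endothelial cells and a T cell pool with fewer CD8 T cells. Fibroblasts were at 21.8% against 8.70% (log2 ratio 1.32 [1.23, 1.42]), endothelial cells at 8.12% against 3.38% (1.27 [1.12, 1.42]) and cancer cells at 18.3% against 29.8% (-0.70 [-0.77, -0.64]). Cluster 4, called fibroblast by the rule written first, was 1.09% of combo and 5.65% of anti-PD-1 cells, so the size of the fibroblast ratio depended on naming. The cancer cell direction depended on naming: with a class given to each cell they were at 12.0% against 10.2% (0.24). Neutrophils were at 2.07% against 4.93% (-1.25 [-1.45, -1.07]), T cells at 9.43% against 12.3% (-0.38 [-0.48, -0.28]) and macrophages at 28.3% against 30.8% (-0.12 [-0.18, -0.06]). With cancer and immune cells as the whole the macrophage ratio was 0.25 and the T cell ratio -0.00948. CD8 T cells were a smaller part of T and NK cells (-1.02 [-1.17, -0.87]) and Treg cells at 24.3% against 12.8% (0.92 [0.69, 1.16]). All 15 cytotoxic effector genes were lower in the T cell class. The interferon gamma and MHC class I list was at -1.47 in cancer cells and -0.47 in macrophages, where the alternative list was at 0.70.

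The comparison of combo with anti-LIF asks what adding the checkpoint antibody to anti-LIF went along with. Most class shares differed little. T cells had a log2 ratio of 0.05 [-0.06, 0.15], cancer cells -0.01 [-0.08, 0.07], fibroblasts -0.04 [-0.11, 0.03] and endothelial cells 0.10 [-0.01, 0.22], each with an interval that held 0. With a class given to each cell the cancer cell ratio was 0.22. The T cell ratio was 0.37 with only cells of at least 1000 UMIs and 0.22 with at least 500 genes. Skeletal muscle cells were at 0.890% against 0.171%. NK cells were higher (0.88 [0.44, 1.36]), as were mast cells (1.09 [0.69, 1.52]) and neutrophils (0.35 [0.11, 0.60]), and macrophages were lower (-0.19 [-0.25, -0.13]). CD8 T cells were again a smaller part of T and NK cells (-0.24 [-0.43, -0.06]). The interferon gamma and MHC class I list was at -0.19 in cancer cells and -0.15 in macrophages.

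**Figure D4:**
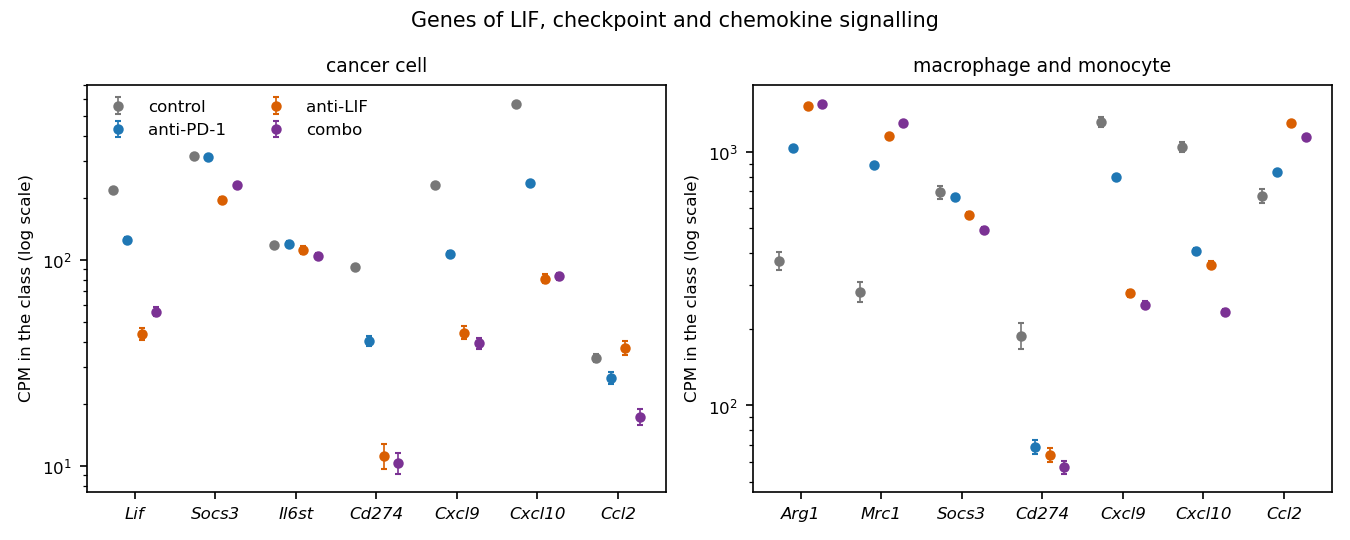
CPM (vertical log axis) of single genes in named classes for the control, anti-PD-1, anti-LIF and combo libraries; points are 1 library each and error bars are exact 95% Poisson intervals for counting error. Lif in cancer cells was at 218, 124, 43.5 and 55.7 CPM, and Cd274 in cancer cells was at 91.9, 40.2, 11.1 and 10.2 CPM.

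The LIF pathway was read directly as well. Lif, on chromosome 11 from 4257557 to 4272514 in the mm10 build, was in cancer cells at 218 CPM in control, 124 in anti-PD-1, 43.5 in anti-LIF and 55.7 in combo. Within cancer cell cluster 4, which Lif marks, it was at 359, 288, 171 and 312 CPM, so much of the lower class value goes with fewer cells of that cluster. In fibroblasts Lif was at 84.7, 126, 77.9 and 73.6 CPM. Cancer cells held 81.0% of the Lif UMIs in control and 70.3% in anti-PD-1, but 32.0% in anti-LIF and 40.0% in combo, where fibroblasts held 46.5% and 44.5%. The receptor gene Lifr was near the floor in cancer cells, at 2.11 CPM in control, but reached 18.1, 41.8, 45.4 and 56.7 CPM in macrophages and 26.5, 21.7, 23.5 and 27.0 CPM in fibroblasts. The shared receptor gene Il6st was even in cancer cells, at 118, 119, 112 and 104 CPM. Socs3, a feedback inhibitor that STAT3 switches on, was at 320, 314, 195 and 229 CPM in cancer cells, at 695, 663, 565 and 495 CPM in macrophages, and at 112, 144, 280 and 226 CPM in T cells. The LIF family list in cancer cells was at -0.25, -0.97 and -0.31 in anti-PD-1, anti-LIF and combo, with Il6 at 95.1 CPM in control against 19.7, 5.11 and 3.31 CPM. The list's values depended on the processing: with the mean over cells they were 0.0538, -0.14 and 0.0158, with a class given to each cell anti-LIF was at -0.11, and with the first naming rule anti-PD-1 was at 0.0433. In macrophages the list was at -0.20, 0.09 and 0.37, and STAT3 targets were at 0.12, 0.09 and 0.14. In T cells STAT3 targets were at 0.11, 0.49 and 0.75. Ccl2, a monocyte-attracting chemokine gene, was at 672, 833, 1303 and 1152 CPM in macrophages, and Cd8a at 1054, 1182, 640 and 584 CPM in T cells.

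The other lists fixed in advance are given here for anti-PD-1, anti-LIF and combo against control, in that order. In cancer cells, hypoxia and glycolysis genes were at -0.24, -0.65 and -0.72, led by the hexokinase gene Hk2 (-0.93, -2.06 and -1.84). Inflammatory fibroblast genes were at -0.76, -2.01 and -0.71, but at -0.42, -0.79 and 0.15 with the first naming rule, and the combo value was 0.0475 with a class given to each cell. Epithelial genes were at -0.83, 0.39 and 0.49, contractile fibroblast genes at 0.81, 0.15 and 0.33, and collagen genes at 0.35, 0.24 and 0.09. Within the 4 cancer cell clusters the anti-LIF values were between -0.11 and 0.77 for contractile genes and between 0.42 and 1.03 for collagen genes. The mix of clusters thus weighs on the class values of these lists. Apoptosis genes were at -0.16, -0.52 and -0.37, mesenchymal transition genes at 0.24, -0.11 and -0.07, and dissociation stress genes at -0.06, -0.09 and -0.19. In macrophages, MHC class II genes were at -0.59, -0.57 and -0.55, but in the monocyte cluster 10 they were at 0.67, 0.98 and 0.93. Type I interferon genes were at -0.15, -0.34 and -0.34, where the anti-PD-1 value was 0.0849 with the first naming rule and 0.000718 with a class given to each cell. Within clusters 3, 6 and 10 they were between -0.61 and -0.29 in anti-PD-1, -0.60 and -0.18 in anti-LIF, and -1.06 and -0.70 in combo. In the class, inflammatory macrophage genes were at -0.26, -0.01 and -0.23, chemokines at -0.19, -0.05 and -0.14, and complement and lipid genes at -0.14, 0.26 and 0.29. In T cells type I interferon genes were at 0.81, 1.12 and 0.92. The interferon gamma list was at 0.18, 0.18 and 0.25, near all genes, and proliferation genes were at -0.27, 0.06 and -0.12. Haemoglobin genes in anti-PD-1 had a median of 6.67 in cancer cells, with Hbb-bs at 8.53, which goes with red cells in that library.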

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

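All of the tests of the 3 patterns weighed here were chosen only after the results were seen.

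In the control library T cells were frequent and macrophages rare, with 12.5 T cells per macrophage against 0.400 in anti-PD-1, 0.283 in anti-LIF and 0.333 in combo. The control library's higher lowest UMI count may have lost macrophages, but with a common minimum in all libraries its ratio was still 31.7 times the highest treated one. Dilution by cells that are neither T cells nor macrophages would leave T cells per macrophage alone, and that ratio differed 31.2-fold. Surrounding tissue that brought its own macrophages cannot be told apart from an antibody effect: the ratio still differed 30.7-fold without cluster 16, led by resident macrophage genes such as Lyve1, but such macrophages need not lie in that cluster. Another handling of the control tissue or a wrong label (median mitochondrial share 9.28%) and an effect of either antibody stay open too, since each group is 1 library.

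A set of 20 genes measured in 6 classes, with the highest class at most 4 times the median of the classes and 16 times the lowest, among them Cct7, Ppp1ca, Psmb5, Mapk3 and Arhgdia, was higher past 2-fold in all 6 classes in both single-antibody libraries, with medians of 1.45 and 1.59. An effect of either antibody that also holds in combination cannot be told apart from other differences. The combo median was only 0.54, but the genes were picked in the 2 libraries it is set against. Among all 7070 genes at a similar level in the 6 classes, combo had 9 higher past 2-fold in all 6 classes and 1 lower. The same counts were 22 and 1 in anti-PD-1 and 41 and 1 in anti-LIF. GC content of the 3' ends is 54.1% at the median for the 20 genes against 45.8% for all, yet genes in the same GC decile had a median of at most 0.13. A difference in sequencing or counting between libraries cannot be told apart from the groups for these 20 genes, since the labels do not give each library's instrument. Cct7 and Ppp1ca are therefore poor candidates for an antibody effect specific to cancer cells or T cells.

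Interferon gamma and MHC class I genes were lower in the cancer cells of each treated library. RNA of T cells and macrophages counted in control cancer cells could raise the control level, but it made up 0.280% and 0.0730% of their UMIs, and after its subtraction the anti-LIF median was -1.96. Fewer cells of cluster 4, which with 41.0% held more control cancer cells than any other cluster, may contribute. With clusters weighted as in control the median was -1.09 in place of -1.93, yet more than 1 part in 2 of the change remained. Less Ifng RNA in the treated tumours stays a candidate explanation. Ifng CPM are here of all UMIs of a library's kept cells, not of a class. They were 35.4 in control, 7.79 in anti-LIF and 4.23 in combo. Anti-PD-1 lay between control and anti-LIF, the order of the list, and control was 3.21-fold above the highest treated library. These values also go with the T cell share, at 35.8% in control and between 9.13% and 12.3% in the treated libraries. In CD8 T cells alone Ifng was higher than control in anti-PD-1 and anti-LIF and about even in combo. With 4 libraries less Ifng RNA cannot be told apart from other differences between them.

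For the values in this paragraph, anti-LIF against control and combo against anti-PD-1 went in opposite directions, each by more than its counting interval. These are differences between single libraries, and every value without anti-PD-1 rests on the same control library. The differences themselves were not tested. The macrophage share was higher with anti-LIF alone and slightly lower when it was added to anti-PD-1, a log2 difference of -3.61. With cancer and immune cells as the whole, the ratio of combo against anti-PD-1 was 0.25. Only control was low in this share, at 2.88% against 28.3% to 32.3% in the treated libraries. The red blood cell share differed by -7.68, from few cells in all. Control had 0 red blood cells, so this value rests on the 0.5 counts added and has no exact size. The NK share of T and NK cells differed by 1.23 and the share of cells in unnamed clusters by 0.79. In cancer cells the contractile fibroblast list differed by -0.45 and the collagen list by -0.47, but with anti-LIF alone they were at 0.15 and 0.24, near the 0.22 of all genes. In CD8 T cells proliferation genes differed by -0.68 and cytotoxic effectors by -0.57. In fibroblasts type I interferon genes differed by 0.37, proliferation genes by -0.63 and inflammatory fibroblast genes by 0.81, and in endothelial cells proliferation genes by -1.31. In neutrophils STAT3 targets differed by 0.92, proliferation genes by -3.45, chemokines by 1.18, suppressive neutrophil genes by 1.53 and inflammatory macrophage genes by 2.15. In dendritic cells type I interferon genes differed by -1.68, proliferation genes by 0.77, MHC class II genes by -0.65 and inflammatory macrophage genes by -1.11.

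Many of these list values go with the mix of clusters. Neutrophil precursor cluster 34 held 0% of neutrophils in control, 25.4% in anti-PD-1, 21.1% in anti-LIF and 3.54% in combo. In the mature cluster 14 the 2 comparisons, anti-LIF against control and combo against anti-PD-1, had opposite directions only for inflammatory macrophage genes (-0.38 and 0.33). STAT3 targets were at 0.21 and 0.22 there, chemokines at -0.20 and -0.42 and suppressive neutrophil genes at 0.00280 and 0.0558, and proliferation genes had too few counts. In fibroblasts the 2 directions of the class were seen in 1 of 4 clusters for type I interferon genes, 2 of 4 for proliferation genes and 1 of 4 for inflammatory fibroblast genes. Fibroblast cluster 13, which inflammatory genes mark, held 6.39% in anti-PD-1 and 22.1% in combo. In cancer cells they were seen in 0 of 4 clusters for the contractile list and 2 of 4 for the collagen list, which was between 0.42 and 1.03 with anti-LIF alone and between -0.56 and 0.30 when it was added. In dendritic cells they were seen in 1 of 2 clusters for type I interferon, proliferation and MHC class II genes. Both clusters showed them for endothelial proliferation genes and for inflammatory macrophage genes of dendritic cells. In CD8 T cells they were seen, past all genes of the same sub-cluster, in 1 of 2 sub-clusters for proliferation genes and 3 of 6 for cytotoxic effectors.

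Of the unnamed clusters, those given here were a larger part of a treated library than of control, past the counting intervals. Clusters 26, 30, 36 and 37, each with genes of more than 1 class, were not, and cluster 26, with cancer cell and T cell genes, was 2.09% of control. Cluster 22, led by gland genes, was 1.31% of the anti-LIF library. Cluster 24, led by Prg2, Ccr3, Alox15 and F5, genes of eosinophils and resident macrophages, was 1.93% of the combo library. Cluster 28, with cancer cell and macrophage genes, was 1.17% of anti-PD-1, and cluster 29, with B cell and plasmacytoid dendritic cell genes, was 0.625% of it. Cluster 33, led by Ctsk, Acp5, Ocstamp and Mmp9, genes of bone-resorbing cells, was 1.01% of anti-PD-1. Cluster 35, led by salivary gland genes, was 0.884% of the combo library and had no cell in the others.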

How the results depend on the processing

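The alternatives added after the data were seen were a common UMI minimum, removal of the cells with the highest doublet scores, cancer and immune cells as the whole, lists within single clusters, and the naming rules that were written first and replaced once their names were seen. No paired analysis was possible because each group is 1 library. A value counts as kept where it stayed within the counting interval of the first choice. Of 141 log2 ratios of class shares, 93 were kept, 46 moved and 2 reversed. Of 18 subset ratios 13 were kept and 5 moved. For the interferon gamma list in macrophages 34 of 45 values were kept and 11 moved. For the other lists 499 of 675 were kept, 167 moved and 9 reversed. For the named genes 285 of 360 were kept, 75 moved and 0 reversed, and the same 72 were named with a lower UMI minimum. For each value below that moved or reversed, the cause was not tested.

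With the first naming rule, cluster 4 counts as fibroblast and mixed clusters join T cells, macrophages and neutrophils. The exhaustion list in T cells then became 0.0294 under anti-LIF and 0.12 under combo. The type I interferon list in macrophages became 0.0849 under anti-PD-1, the LIF family list in cancer cells 0.0433 under anti-PD-1 and the inflammatory fibroblast list 0.15 under combo. Each of these 5 reversed. Among values that moved, cancer cell ratios were -0.73 for anti-LIF and -0.68 for combo, and macrophage ratios were 3.18, 3.21 and 3.03 for anti-PD-1, anti-LIF and combo. The neutrophil ratios of anti-PD-1 and combo were 0.67 and -0.63, and the interferon gamma list in their macrophages -0.43 and -1.03. With the first subset rule, CD8 T cell ratios were 0.39, -0.47 and -0.56; the first of these was -0.05 before, with an interval that held 0.

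The neutrophil share of combo against control became 0.14 with only cells of at least 1000 UMIs and 0.0378 with cancer and immune cells as the whole. With a class given to each cell, the type I interferon list in macrophages under anti-PD-1 became 0.000718 and the inflammatory fibroblast list in cancer cells under combo 0.0475. With the mean over cells of each cell's CPM, the LIF family list in cancer cells became 0.0538 under anti-PD-1 and 0.0158 under combo.

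The values below are in the order anti-PD-1, anti-LIF, combo against control where 3 are given. With mitochondrial UMIs up to 10%, cancer cell ratios were -0.46, -1.17 and -1.21, T cell ratios -1.66, -2.45 and -2.30, and neutrophil ratios 0.64, -1.10 and -0.77. The macrophage ratio of anti-LIF was 3.35 and the interferon gamma list in combo macrophages -1.33. With at least 500 genes, neutrophil ratios were 1.49, -0.52 and -0.0376, and the T cell ratio of anti-LIF was -2.07. With only cells of at least 1000 UMIs, the neutrophil ratios of anti-PD-1 and anti-LIF were 1.82 and -0.17. Their T cell ratios were -1.69 and -2.25, and the cancer cell ratio of combo was -1.12. At resolution 0.5 the neutrophil ratios of anti-PD-1 and combo were 0.67 and -0.63.

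With a class given to each cell, cancer cell ratios were -0.71, -0.70 and -0.47, macrophage ratios 3.17, 3.17 and 3.05, and the interferon gamma list in macrophages -0.50, -0.72 and -1.05. Neutrophil ratios of anti-LIF and combo were -0.23 and -0.0398. For combo against anti-PD-1 the cancer cell ratio was then 0.24 in place of -0.70. With cancer and immune cells as the whole, cancer cell ratios were -0.26, -0.63 and -0.59, and the macrophage ratio of combo against anti-PD-1 was 0.25 in place of -0.12. The T cell ratios of anti-LIF and combo were -1.59 and -1.48, their macrophage ratios 3.87 and 3.74, and the neutrophil ratio of anti-LIF -0.37. With immune cells as the whole, the T cell ratios of anti-PD-1 and combo were -1.64 and -1.81. With subsets given per cell, the combo ratios were -0.84 for CD8 T cells and 1.86 for Treg cells.

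The interferon gamma list in macrophages of anti-PD-1 and combo was -0.74 and -1.33 with TMM scaling and -0.76 and -1.34 with median-of-ratios scaling. In combo it was -1.05 with the mean over cells of each cell's CPM. Each macrophage ratio against control rests on 536 control macrophages.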

Other observations

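In dendritic cells type I interferon genes were at 1.67, 1.13 and 0.72 in anti-PD-1, anti-LIF and combo against control, with the antiviral Oas1a at 3.18 in anti-PD-1 and 2.36 in combo, from 5 control UMIs. The list was at 2.05, 1.91 and 1.21 in cluster 15 but at 0.0697, -0.73 and -0.12 in cluster 27. MHC class II genes were at 0.56, 0.55 and 0.49, while alternative macrophage genes were at 1.44, 3.53 and 3.67, led in anti-PD-1 by Mrc1 (19.7 CPM in control, 178 in anti-PD-1). RNA of other cells is part of these values. Genes of macrophages were at 0.779% of their macrophage level in control dendritic cells and at 4.16%, 3.19% and 3.32% in the treated ones, and 5 T cell genes were at 26.4% of their T cell level in control and at 4.40%, 2.16% and 2.77%. After subtraction of both, the alternative macrophage list was at 1.08, 0.77 and 0.54, type I interferon genes at 2.04, 1.81 and 1.43 and MHC class II genes at 0.54, 0.55 and 0.48. In neutrophils interferon gamma genes were at -1.11 in anti-PD-1 and -1.28 in combo, and lower in anti-LIF too, with the inflammatory macrophage list at -1.97, -0.87 and -0.54 and suppressive neutrophil genes at -1.04, -0.58 and -0.04. Ccl3, a chemokine gene, was at -3.52, -1.77 and -1.54 there. Proliferation genes in neutrophils were at 3.19, 2.07 and 1.08, which goes with precursor cluster 34 of 0 control, 180 anti-PD-1, 48 anti-LIF and 12 combo cells. The other lists go with it in part: in the mature cluster 14 suppressive neutrophil genes were at 0.0480, 0.00280 and -0.22, inflammatory macrophage genes at -0.79, -0.38 and -0.33 and interferon gamma genes at -0.52, -0.58 and -1.17.

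The fibroblast class had higher contractile RNA in each treated library, with that list at 0.64, 0.63 and 0.53 and collagen genes at 0.25, 0.35 and 0.21. The mix of fibroblast clusters differed: cluster 13 held 24.9% in control and 6.39%, 12.6% and 22.1% in the treated libraries, and cluster 5 held 32.1% against 49.0%, 45.7% and 37.8%. Within the 4 clusters the contractile list was between -0.12 and 0.44 in anti-PD-1, 0.21 and 0.84 in anti-LIF, and -0.21 and 0.78 in combo, so part of the class value goes with the mix. Acta2, the smooth muscle actin gene, was at 1.10, 0.84 and 1.11 and Timp1, a protease inhibitor gene, at 1.45, 0.99 and 0.96. Interferon gamma genes were lower in fibroblasts (-0.74, -0.68 and -0.70) and endothelial cells (-0.50, -0.31 and -0.58). Endothelial activation genes were at -0.02, -0.04 and -0.17, with the tip cell gene Esm1 at -0.91, -1.32 and -1.18. Inflammatory fibroblast genes in fibroblasts were at -0.62, -0.16 and 0.04, but between -0.20 and 0.0134 within the 4 clusters in anti-PD-1, so the mix carries most of that value. NK cells had higher cytotoxic effector RNA, at 0.99, 0.71 and 0.77. They came from sub-clusters 6 and 10 in changed proportion, with sub-cluster 10 at 34.9% of NK cells in control and 59.8%, 46.3% and 69.1% in the treated libraries. Within sub-cluster 6 the list was at 0.71, 0.42 and 0.0434 and within sub-cluster 10 at 0.71, 0.51 and 0.25, so most of the combo value goes with the mix. Treg cells were lower, at -0.47, -0.41 and -1.12. Mast cells were at 0.451% of cells in control, 0.869% in anti-PD-1, 0.507% in anti-LIF and 1.09% in combo.

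RNA of other tissue was present outside its own cells. In combo cells outside cluster 35, Bpifa2 was at 228 CPM, Smr3a at 85.2 CPM and Amy1 at 25.5 CPM. Haemoglobin gene Hbb-bs was at 32.6 CPM in anti-PD-1 cells outside the red cell class, 0.0782 in control, 0.887 in anti-LIF and 2.38 in combo. In the T cell class, the macrophage gene Mrc1 was at 0.571 CPM in control and at 14.9, 14.1 and 21.9 CPM in the treated libraries.

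Lists with small or unstable values were these. In macrophages, for anti-PD-1, anti-LIF and combo against control, hypoxia genes were at 0.02, -0.10 and -0.05, apoptosis genes at 0.15, 0.18 and 0.18, stress genes at -0.03, 0.21 and 0.29 and proliferation genes at 0.09, -0.02 and -0.16. In T cells hypoxia genes were at 0.11, 0.05 and 0.12, apoptosis genes at 0.03, 0.13 and 0.14 and stress genes at 0.03, 0.54 and 0.47. The exhaustion list in T cells was at -0.22 in anti-LIF and -0.22 in combo, and it took the other sign, at 0.0294 and 0.12, when cluster 26, with cancer cell and T cell genes, was counted as T cells.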
